A study of Mus musculus with 5 samples.

How the data were processed

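Open chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse embryos of the CD1 stock. The labels give 2 libraries of distal forelimb ectoderm and 2 of distal hindlimb ectoderm, all taken at embryonic day 14.5, and 1 library of forebrain taken at embryonic day 13.5. Per the labels' protocols, ectoderm was freed from the underlying mesoderm with trypsin and forebrain was digested with collagenase, so tissue, stage and dissociation differ together between ectoderm and forebrain. The labels do not say whether replicates came from separate embryos or litters, so the spread between them may be technical.

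The submitters' processing notes name cutadapt 1.16, Bowtie2 2.3.5, Picard, bedtools and MACS2 2.1.1.20160309, and the mm10 build. Whether reads were shifted to the transposase insertion site is not given in the sources used here. The authors deposited 1 peak list per library, so peaks were called per sample and not on pooled replicates. The deposited lists give, for each peak, an interval, a summit, a score (the authors' rescaled significance, not used further), a fold enrichment at the summit and −log10 of its p-value and q-value. The smallest −log10 q in the deposited lists lay between 1.30 and 1.31 in every library, the value of a q threshold of 0.05. A fold or −log10 p is the authors' value for that peak in its own list and was used to describe, rank or filter peaks within that list. Summit pileups recovered from them were also compared between limbs during the work, but this was set aside and is not reported, because the values belong to their own lists. The closing section sets median folds of the ectoderm libraries side by side once, and draws no verdict from them for the same reason.

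Peaks on chromosomes 1 to 19, X and Y were kept, and an interval listed with several summits was counted as 1 peak. The lists hold no read totals. The relation between fold and p under the Poisson model of MACS2 was therefore solved for the summit pileup and local background of each peak. The stated p was met within 0.01 in −log10 units, with a proportionally wider tolerance for very small p, for 100% of peaks in each library. The most frequent background value served as the library's background rate. Under MACS2 it is proportional to the reads used times their extension length, so it compares depths only if the same extension was used in each library. It was 3.1 to 4.62 reads per position over the 5 libraries. All peaks were merged into regions, with 1 bp of overlap enough to join them, and a library was said to have a peak in a region if any of its peaks lay there. Forelimb-only regions had a peak in both forelimb libraries and in neither hindlimb library, and hindlimb-only regions the opposite. Ectoderm-only regions had a peak in all 4 ectoderm libraries and not in forebrain, and forebrain-only regions had a peak in forebrain and in no ectoderm library. A missing peak means that none was called at the authors' threshold, not that the site was closed.

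Genes came from a RefSeq table of the same assembly (GRCm38.p6), which gives the ends of each gene without strand or exons. Of its genes, 21883 protein-coding ones were used. A design based on start sites had been planned; instead, a region was called near a gene end when its strongest summit lay within 1 kb of either end of a protein-coding gene, and was assigned to the nearest protein-coding gene within 100 kb, at distance 0 inside a gene. Of 252 entries in 16 gene lists fixed before the data were examined, 1 was not found, and the limb identity list shares 3 genes with the HoxC list. For each list, the ectoderm-only share of its ectoderm-only and forebrain-only regions was ranked among 10000 random lists matched on regions per gene in 10 bins. The count of ectoderm-only regions in a window from 300 kb beyond the Hox13 end to 100 kb beyond the other end of each Hox cluster was ranked among 10000 random windows of equal length holding at least 1 region. These percentiles describe the libraries and are not tests. No p-value is given for any comparison: forebrain has 1 library, and 4 ectoderm libraries can be split evenly in only 3 ways. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

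The genes named were fixed by a rule written at the same stage. They are the 10 genes with the largest difference in each limb direction, every limb identity and HoxC gene, the 10 genes with most ectoderm-only and the 10 with most forebrain-only regions, and up to 4 members per list with the largest difference. In the HoxC window the rule takes regions with a peak in at least 2 ectoderm libraries and none in forebrain. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen. That holds also for the epidermis, progenitor and neuron genes named for a gene-end peak in 1 tissue and not the other. Alternatives were a −log10 q of 5 or more, lists shortened to the length of the shortest by −log10 p, presence judged by summits within 250 bp, autosomes only, gene assignment within 20 kb, 2.5 kb around gene ends, overlap of at least 50% of the shorter peak, and leaving out each ectoderm library. A stricter threshold for presence only, with any deposited peak counting against absence, was added after the data were seen. Gene lists were thus examined in 11 settings, the main one included. A planned motif contrast was not run, as no genome sequence was used here.

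Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used. On 20000 simulated regions the 5 classes were recovered at 100%. The simulated regions lay too far apart to join, so errors from merging neighbouring peaks were not covered. A planted list of 20 genes with an ectoderm share of 25% against 7% elsewhere reached percentile 100 among 21883 genes, and 6.5% of 200 unplanted lists fell outside the central 95%. Pileups of 20000 simulated peaks were recovered exactly in 100% of cases.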

Results

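Accessible chromatin was profiled in the ectoderm of the distal forelimb and hindlimb of E14.5 mouse embryos, the tissue that gives rise to epidermis, hair and nails, and in E13.5 forebrain as a tissue outside the skin. Each limb had 2 libraries and forebrain had 1. The deposited lists held 73830 and 73718 distinct peaks in forelimb replicates 1 and 2. Hindlimb replicates 1 and 2 had 51510 and 78147 peaks, and forebrain had 120297. Read totals were not used here. The background rates implied by the peak statistics, a relative measure of depth, were 3.1 and 3.68 in forelimb, 4.36 and 4.12 in hindlimb and 4.62 in forebrain reads per summit position. At those rates, the smallest summit pileup called over plain background was 10 and 11 in forelimb, 12 in both hindlimb libraries and 12 in forebrain.

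Replicates shared their strongest peaks and differed in their weakest ones. Of the peaks in forelimb replicate 1, 53.5% overlapped a peak of forelimb replicate 2, and 54.3% the other way round. With forelimb replicate 1 peaks divided into 5 equal parts by fold enrichment within that list, the share was 98.2% in the highest part and 21.8% in the lowest. Of the hindlimb replicate 1 peaks, 50.7% overlapped a peak of hindlimb replicate 2, but only 32.5% of the longer hindlimb replicate 2 list overlapped a peak of replicate 1. Forelimb replicate 1 overlapped hindlimb replicate 2 at 55.7%, more than it overlapped its own replicate. The hindlimb replicate 2 list was also longer than that of forelimb replicate 2. In the highest part by fold the order was reversed, at 97.7% with hindlimb replicate 2 and 98.2% with its own replicate. Merging all peaks gave 231612 regions, of which 164701 (71.1%) had a peak in 1 library only.

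**Figure D1:**
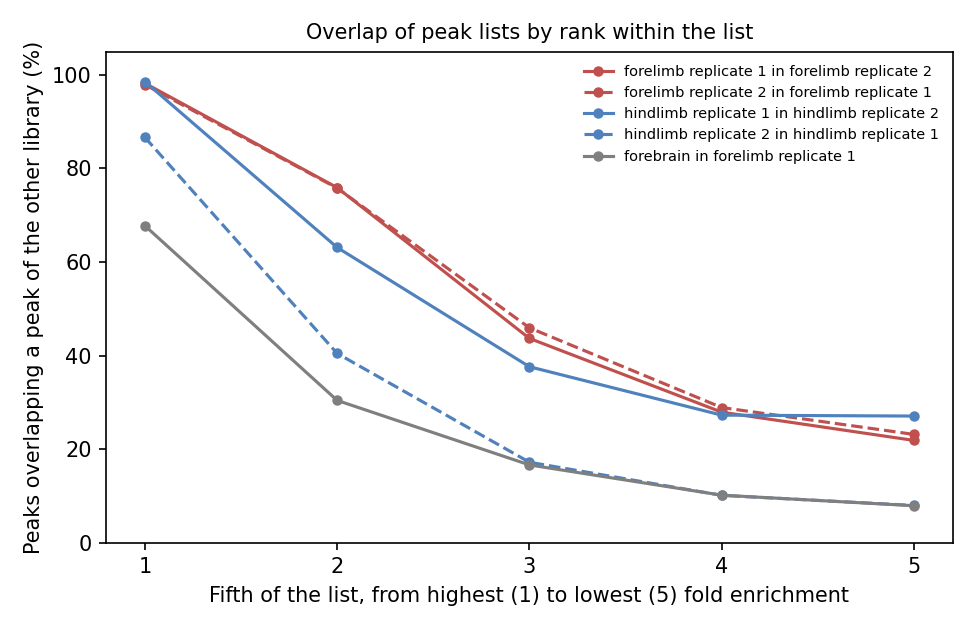
Percent of peaks (vertical axis) of one library that overlap a peak of another by at least 1 bp, for each of 5 equal parts of the list ranked by the authors' fold enrichment within that list (horizontal axis, 1 highest). The share for forelimb replicate 1 against its replicate falls from 98.2% to 21.8%, and that for forebrain against forelimb replicate 1 from 67.8% to 7.88%.

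The comparison of limb ectoderm with forebrain addressed which regions are open in the developing skin. A set of 20977 regions had a peak in all 4 ectoderm libraries, and 74.2% of these also had one in forebrain. The remaining 5403 regions were ectoderm-only, and 76775 regions were forebrain-only. Regions with a peak in all 5 libraries numbered 15574. Of these shared regions, 57.0% (95% interval 56.2 to 57.8) lay within 1 kb of a gene end, against 3.81% (3.32 to 4.36) of ectoderm-only and 3.13% (3.01 to 3.26) of forebrain-only regions. Ectoderm-only regions lay inside protein-coding genes in 44.1% of cases and beyond 100 kb of any in 20.4%. As a background for these counts, each ectoderm library was set in the place of forebrain: 386, 589, 6491 and 291 regions were missing only from forelimb replicates 1 and 2 and hindlimb replicates 1 and 2. Regions found in only that library numbered between 20784 and 24214 for the ectoderm libraries. The number of regions missing from hindlimb replicate 1 alone thus exceeded the ectoderm-only count, and without that library the ectoderm-only count was 10839. Requiring 4 libraries on the ectoderm side and 1 on the forebrain side makes the counts unequal by construction, and lists of equal length gave 24074 forebrain-only regions. A −log10 q of 5 or more gave 3515 ectoderm-only and 49277 forebrain-only regions, and the order of their gene-end shares turned round there, at 4.04% and 4.77%. Within 2.5 kb of a gene end the shares were 7.76% and 6.31%.

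Genes of the epidermis had the largest ectoderm share of the lists with more than 11 regions in the main setting. HoxC genes, with 11 regions there, had a larger share (36.4%). They passed that number without forelimb replicate 1, at 50% against 21.1% for basal epidermis genes. They also did so without hindlimb replicate 1, at 46.2% against 33.9%. Over all genes, 6.83% of assigned ectoderm-only and forebrain-only regions were ectoderm-only, against 12.6% without hindlimb replicate 1 and 20.6% with lists of equal length. Near the 22 basal epidermis genes the counts were 32 and 113, an ectoderm share of 22.1%, above the central 95% of matched random lists (2.63% to 11.4%) and at percentile 100. By the rule for named genes, these included Dst, which encodes a hemidesmosomal linker, with 3 ectoderm-only and 27 forebrain-only regions, and Lama3, a laminin chain of the basement membrane, with 3 and 10. Itga6 and Klf5 each had 0 and 9. Among members chosen after their values were seen, Trp63, the transcription factor at the head of the stratified epithelial programme, had 6 ectoderm-only and 10 forebrain-only regions. The desmosomal gene Perp had 3 and 5, and Grhl3, a regulator of the skin barrier, had 2 and 1. Krt14, the basal keratin, had 1 and 0. In all, 15 of the 22 genes had at least 1 ectoderm-only region, and 17 had at least 1 forebrain-only region. A peak at a gene end was present in all 4 ectoderm libraries and absent from forebrain for Tfap2a, an ectodermal transcription factor, and the reverse, a peak in forebrain and in no ectoderm library, was found for the related Tfap2c. Counted per library, 19 and 19 of the 22 genes had a gene-end peak in forelimb replicates 1 and 2. The counts were 13 and 19 in hindlimb replicates 1 and 2 and 14 in forebrain. Differentiated epidermis genes had 10 ectoderm-only and 39 forebrain-only regions, a share of 20.4% at percentile 99.1. The rule named Abca12, a lipid transporter of the skin barrier (1 and 15), Klf4 (1 and 9), Tgm3 (1 and 5) and Dsc1 (1 and 3). Gene-end peaks in all 4 ectoderm libraries and not in forebrain were found at Sprr1a, Krtdap, Casp14 and Abca12, genes of late keratinocyte differentiation, and the reverse was found at Krt10, a keratin of differentiating epidermis. The basal list stood above the central range in all 11 settings examined. The differentiated list did so in 10 of 11, the exception being lists of equal length at percentile 97.1, where its share was 44.4% and that of the basal list 56.7%. Without hindlimb replicate 1 the basal counts were 60 and 117, a share of 33.9%, and the differentiated counts were 17 and 43, a share of 28.3%.

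Forebrain progenitor genes showed the opposite balance, and neuron genes did not stand apart from random lists. Forebrain progenitor genes had 4 ectoderm-only and 167 forebrain-only regions, a share of 2.34% at percentile 2.05, just below the central 95% of matched random lists, which began at 2.46%. Sox2, a neural progenitor factor, had 0 and 23, Pax6 had 0 and 16, Otx2 had 0 and 15, and Nkx2-1 had 1 and 15. A gene-end peak was present in forebrain and in no ectoderm library at Pax6, Hes5, Fabp7, Gsx2, Otx2 and Nkx2-1. This list lay below the central range in 8 of 11 settings, and within it at a −log10 q of 5 or more (percentile 3.84), on autosomes only (2.74) and with the stricter threshold for presence only (3.67). Its share was 4.47% without hindlimb replicate 1, at percentile 0.16, and 7.14% with lists of equal length, at percentile 1.19. Neuron genes had 19 and 286 regions, a share of 6.23% at percentile 53.6, and without hindlimb replicate 1 they had 32 and 294, a share of 9.82% at percentile 26.9. Syt1, a sensor of transmitter release, had 1 and 41, Rbfox3 1 and 26, and Map2 2 and 21. At gene ends, Dcx, Neurod1, Neurod2, Fezf2, Gad1, Gad2 and Slc32a1 had a peak in forebrain and in no ectoderm library.

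Lists for hair and nail appendages, for the apical ectodermal ridge and for other cell types lay within the range of random lists in the main setting. Appendage genes had 9 ectoderm-only and 68 forebrain-only regions (11.7%, percentile 93.5), led by difference by Lef1 (2 and 15), Bmp2 (0 and 9), Edar (0 and 8) and Shh (0 and 7). Ridge genes had 9 and 73 (percentile 93.3), led by Dlx6 (1 and 12), Rspo2 (0 and 8), Msx2 (1 and 7) and En1 (2 and 8). Markers of cells that a dissection could carry over gave shares of 4.92% for limb mesenchyme (percentile 25.5), 8.24% for melanocytes (percentile 77.0) and 6.17% for endothelium (percentile 51.0). Examples were Runx2 (1 and 15), Mitf (0 and 21) and Kdr (0 and 13). Blood and immune genes had 0 ectoderm-only and 42 forebrain-only regions at percentile 3.49, with Runx1 at 0 and 16, and 5 and 42 without hindlimb replicate 1. Housekeeping genes had 1 and 20 regions at percentile 37.3, and 17 of 20 had a gene-end peak in all 4 ectoderm libraries. Limb identity genes had 2 and 31 regions at percentile 48.3. Without hindlimb replicate 1 the counts were 15 and 76 for endothelium (percentile 88.9), 8 and 79 for melanocytes (percentile 27.9), 10 and 121 for limb mesenchyme (percentile 6.64), 15 and 76 for ridge (percentile 90.6), 7 and 33 for limb identity (percentile 80.4) and 3 and 20 for housekeeping genes (percentile 47.8). Without hindlimb replicate 2 those for housekeeping genes were 2 and 23, and without forelimb replicate 1 those for blood and immune genes were 2 and 46. With lists of equal length the limb identity counts were 4 and 3 (percentile 96.2), and at a −log10 q of 5 or more the endothelial counts were 1 and 47 (percentile 10.4). The appendage list rose above the central range in 5 of 11 settings, among them the −log10 q of 5 or more (17.0%, percentile 99.0) and the one without hindlimb replicate 1 (21 and 71 regions, percentile 99.1). The others were gene assignment within 20 kb (percentile 98.3), lists of equal length (percentile 99.5) and the stricter threshold for presence only (percentile 99.0). The ridge list did so in 1 of 11, without forelimb replicate 2 (12 and 74 regions, percentile 98.4).

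**Figure D2:**
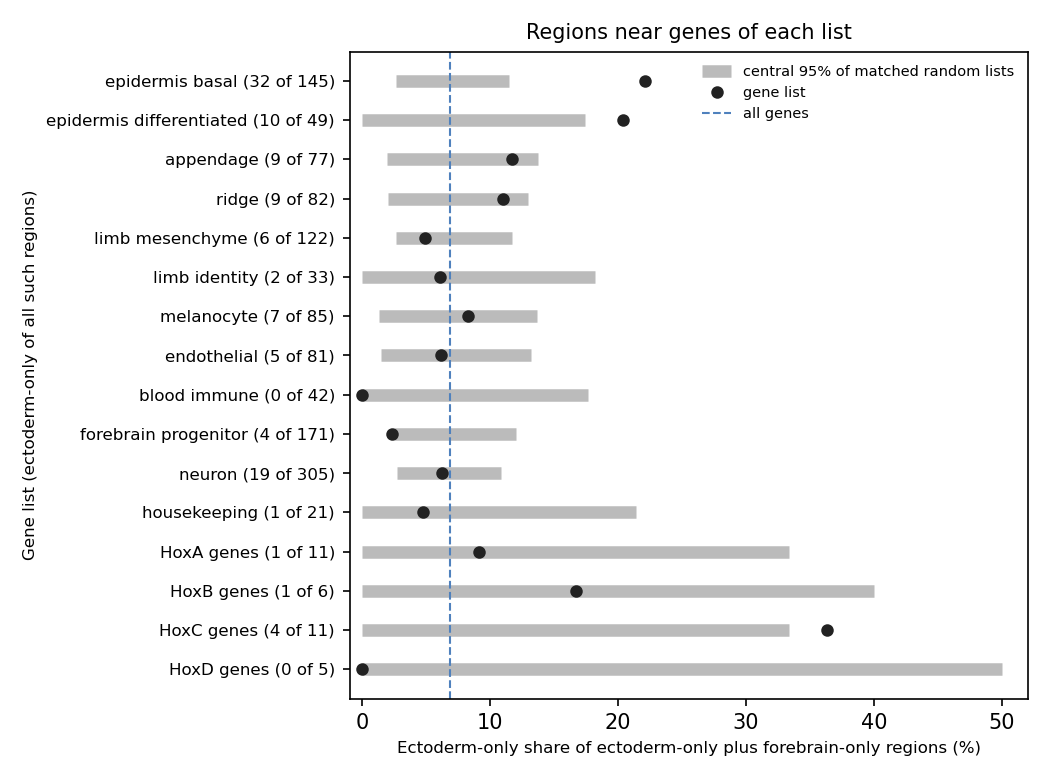
For each gene list (vertical axis, with ectoderm-only regions out of ectoderm-only plus forebrain-only regions), the dot gives the ectoderm-only share in percent (horizontal axis), the grey bar the central 95% of 10000 matched random lists, and the dashed line all genes (6.83%). Basal epidermis (22.1%), differentiated epidermis (20.4%) and HoxC genes (36.4%) lie to the right of their bars.

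Forebrain-only regions were most frequent at Macrod2 (104), Ptprd (97), Lsamp (88), Tenm2 (85), Auts2 (81), Tenm3 (77), Dab1 (76), Cntnap2 (74), Gpc6 (74) and Sox5 (72). Such counts were not adjusted for the regions of any kind assigned to a gene. Those numbered 199 at Macrod2, 210 at Ptprd, 199 at Lsamp and 150 at Sox5, and 33.1% of all regions were forebrain-only. The genes with most ectoderm-only regions included Cwc22 (14, with 2 forebrain-only), Macrod2 (11), Lsamp (9), Zfp970 (9, with 0 forebrain-only), Sfi1 (9, with 3), Tiam1 (8, with 38), Fry (8, with 11), Tenm4 (7, with 64) and Lrp1b (7, with 66). The local background at ectoderm-only peaks of Cwc22, Zfp970 and Sfi1 was 6.12, 2.93 and 2.3 times the library background rate, against 1.46 at ectoderm-only regions outside these loci and Gm14410. For Fry, the difference turned toward ectoderm with lists of equal length (6 more ectoderm-only than forebrain-only regions) and at a −log10 q of 5 or more (1 more).

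The title of the series concerns ectodermal enhancers of Hoxc genes, so the HoxC cluster on chromosome 15 was examined from 102621131 to 103136856 (mm10). This window held 89 regions, of which 8 were ectoderm-only, 17 forebrain-only and 10 present in all 5 libraries. Random windows of the same length held a median of 1 ectoderm-only region, and 8 stood at percentile 99.8. Among 861 windows with a similar number of regions the percentile was 98.7. The HoxB window held 4 ectoderm-only regions (percentile 95.3), and the HoxA and HoxD windows held 1 each (percentiles 57.5 and 57.4). At a −log10 q of 5 or more the HoxC window held 3 ectoderm-only regions, at percentile 96.3, and with the stricter threshold for presence only it also held 3, at percentile 97.0. HoxC genes themselves were assigned 4 ectoderm-only and 7 forebrain-only regions, a share of 36.4% at percentile 98.9, which lay above the central 95% in 6 of 11 settings and within it in 5, with percentiles down to 87.4. Their counts were 7 and 7 without forelimb replicate 1 and 6 and 7 without hindlimb replicate 1. The shares of the HoxA, HoxB and HoxD genes were 9.09%, 16.7% and 0% (0 of 5 regions), at percentiles 55.3, 76.9 and 31.6, and without hindlimb replicate 1 HoxD genes had 1 and 5 regions and the HoxA and HoxB percentiles were 26.5 and 46.1. At a −log10 q of 5 or more the HoxA and HoxC shares were both 25%, at percentiles 87.0 and 94.1. With the stricter threshold for presence only they were 33.3% (1 and 2 regions, percentile 92.2) and 25% (2 and 6, percentile 87.4). The HoxB and HoxD shares were 0% in both settings.

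Of the 8 regions, 3 lay in the 199 kb without protein-coding genes between Calcoco1 and Hoxc13. The strongest of these by rank was 102754418 to 102755484, within the long non-coding gene Gm36560 and 165.9 kb from the near end of Hoxc13. Its fold enrichment was 8.26 and 5.79 in forelimb and 6.66 and 12.6 in hindlimb replicates 1 and 2, each in its own list. Ranked by −log10 p within each list, it lay at percentiles 92.2, 84.0, 94.1 and 96.7. Another region in Gm36560, 102771287 to 102771716, lay 149.6 kb from Hoxc13, and the region 102838200 to 102838612 lay 82.7 kb from Hoxc13 outside any annotated gene. Within the cluster, 102946088 to 102946564 fell in the non-coding gene Hotair, between Hoxc12 and Hoxc11, and 103032733 to 103033063 in Hoxc4. Beyond Hoxc4 lay 103074730 to 103075569, outside any gene, and 103128476 to 103129083, in the gene D930007P13Rik. The remaining region, 102694438 to 102694839, lay between Atp5g2 and Calcoco1. The nearest forebrain peak was 466 bp from that region, 860 bp from 102754418 to 102755484, 1199 bp from 102838200 to 102838612, and at least 2593 bp from each of the other regions. A further 8 regions of the window had a peak in 3 ectoderm libraries and none in forebrain, and 7 had one in 2. Of the 23 regions in these groups, 9 lay between Calcoco1 and Hoxc13, 8 between the outer ends of Hoxc13 and Hoxc4, and 3 beyond Hoxc4, with the rest elsewhere in the window. Gene ends of Hoxc13 and Hoxc10 had a peak in all 5 libraries, and Hoxc12 had one in 3 ectoderm libraries and not in forebrain. Hoxc4, Hoxc6, Hoxc8 and Hoxc9 had none within 1 kb of an end in any library, though the region 102999229 to 102999653 inside Hoxc6 had a peak in all 5.

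**Figure D3:**
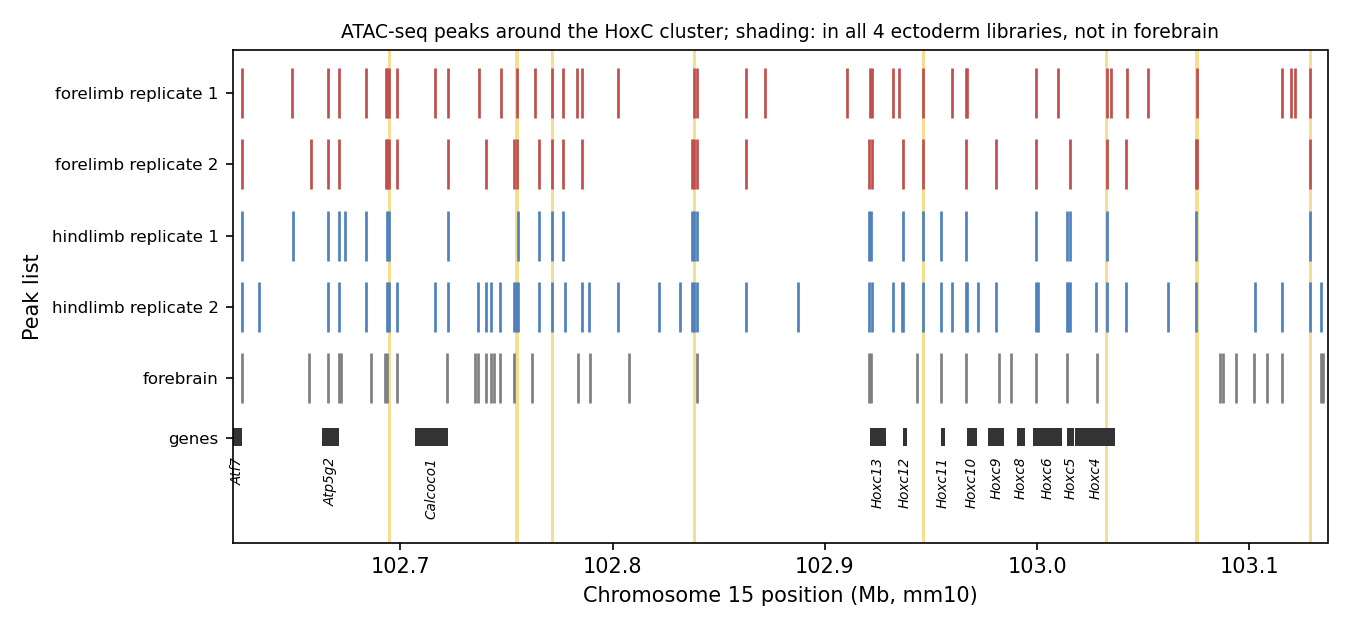
Peaks of the 5 libraries (rows, 1 tick per peak) along chromosome 15 in Mb (mm10) from 102621131 to 103136856, with protein-coding genes drawn to scale at the bottom. Yellow shading marks the 8 regions with a peak in all 4 ectoderm libraries and none in forebrain, 3 of them between Calcoco1 and Hoxc13.

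Forelimb and hindlimb ectoderm were compared to ask where accessibility differs between the limbs. Forelimb-only regions numbered 4573 and hindlimb-only regions 1517, a ratio of 3.01. Limb identity and HoxC genes held few of them. Tbx5, the forelimb selector gene, had 1 forelimb-only and 0 hindlimb-only regions. Hoxc11, a gene of hindlimb mesenchyme, and Hoxc5 each had 0 and 1. These hindlimb-only regions were 102954385 to 102954811, at an end of Hoxc11, and 103014068 to 103014514, at an end of Hoxc5, both on chromosome 15. The hindlimb peaks at Hoxc11 were weak, with a −log10 q of 2.64 and 4.87 in replicates 1 and 2, below the stricter threshold of 5. Those at Hoxc5 had 11.5 and 14.8. Both regions also had a forebrain peak. They were the hindlimb-only regions of the HoxC window, which held 2 (percentile 97.4 among random windows) and 1 forelimb-only region (percentile 59.6). Tbx4, Pitx1, Isl1, Hoxc4, Hoxc6, Hoxc8, Hoxc9, Hoxc10, Hoxc12 and Hoxc13 had neither kind.

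Of the genes with the largest differences, those toward forelimb included Nrxn3 (9 forelimb-only and 1 hindlimb-only), Opcml (7 and 0), Magi2 (6 and 0), Ctnna3 (6 and 0), Dlg2 (7 and 2), Rbfox1 (6 and 1), Xylt1 (5 and 0), Gabrg3 (5 and 0) and Ptprd (5 and 1). Toward hindlimb they were at Tenm3 (1 and 4), Cwc22 (2 and 5), Gm14410 (1 and 4), Lrp1b (1 and 3), and Fto, Lypd6b, Sfi1, Daam1, Barhl2 and Hlcs (0 and 3 each). None of these counts was adjusted for the regions of any kind assigned to a gene. Those numbered 158 at Nrxn3, 180 at Dlg2, 210 at Ptprd, 163 at Tenm3 and 26 at Hlcs. Over all regions, 1.97% were forelimb-only and 0.655% hindlimb-only, so genes with many regions tend to a difference toward forelimb. The local background at ectoderm-only peaks of Cwc22, Sfi1 and Gm14410 was 6.12, 2.3 and 1.28 times the library rate. The difference at Lrp1b turned toward forelimb (1 more) at a −log10 q of 5 or more. Without hindlimb replicate 1 the forelimb-only minus hindlimb-only count was -3 at Nrxn3, -5 at Opcml, -13 at Magi2, -12 at Ctnna3, -18 at Dlg2, -10 at Rbfox1, -11 at Ptprd, 0 at Xylt1 and 1 at Gabrg3. Without hindlimb replicate 2 it was 0 at Nrxn3, -6 at Opcml, -1 at Magi2, -5 at Ctnna3, -5 at Dlg2, -1 at Rbfox1, -3 at Ptprd, 3 at Xylt1 and 0 at Gabrg3. Without forelimb replicate 1 it was 14 at Tenm3, 2 at Cwc22, 5 at Fto, 2 at Lypd6b, 14 at Lrp1b and -1 at Daam1, and without forelimb replicate 2 it was 1 at Tenm3, 4 at Gm14410, 7 at Lrp1b, 0 at Lypd6b and -1 at each of Fto, Daam1, Barhl2 and Hlcs. Over all 4 left-out libraries in turn, every gene listed here with its forelimb-only and hindlimb-only counts moved by over 1.5 times at least once. Differences of this size also arose between libraries grouped across limbs: Lsamp differed by 9 when the replicates 1 were set against the replicates 2, and Cdh13 by 8 in the crossed split.

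At the authors' threshold the limb difference was no larger than that between other groupings of the same libraries, and with lists of equal length it was the largest of the 3 splits. Forelimb-only plus hindlimb-only regions came to 6090. Setting both replicates 1 against both replicates 2 gave 6267, and the crossed split gave 6158. With lists of equal length the limb split gave 4697, against 4465 and 3974, and at a −log10 q of 5 or more it gave 2961, against 4209 and 3958. In each split the side that held hindlimb replicate 1 had fewer regions. The class counts at a −log10 q of 5 or more were 2474 forelimb-only and 487 hindlimb-only, and 1531 and 202 with the stricter threshold for presence only. Leaving out 1 library leaves 1 library to stand for a limb, which raises the counts by construction. Forelimb-only regions numbered 30022 and 29814 without forelimb replicates 1 and 2, and 5076 and 16512 without hindlimb replicates 1 and 2. Hindlimb-only regions numbered 2662, 2599, 29499 and 23882 in the same order, so that they outnumbered forelimb-only regions whenever a hindlimb library was left out.

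**Figure D4:**
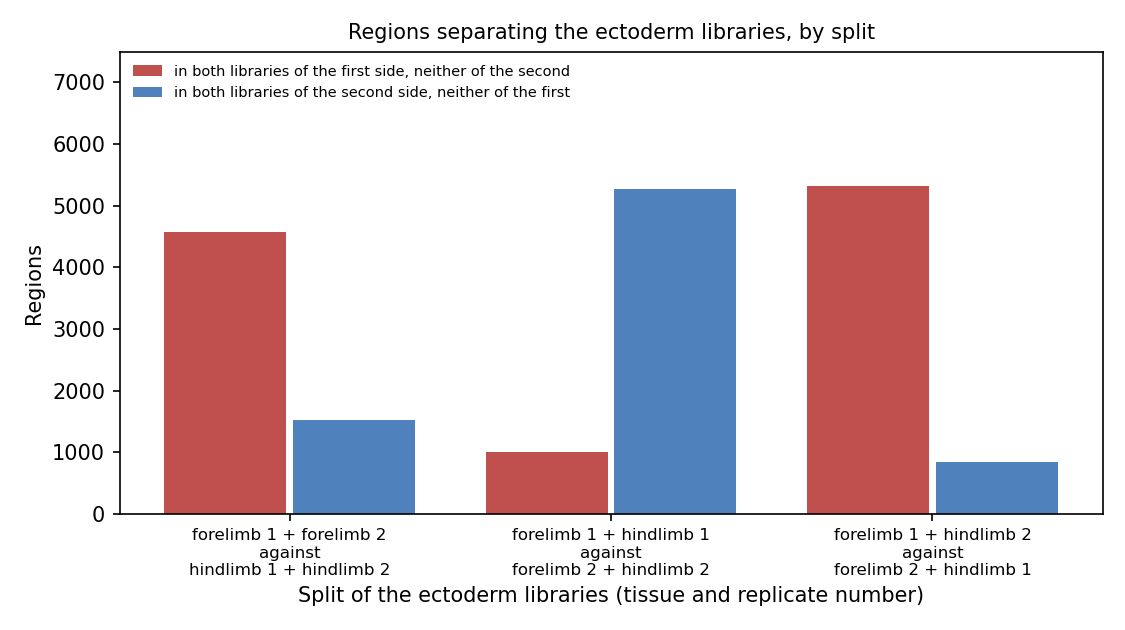
Number of regions (vertical axis) with a peak in both libraries of one side and in neither of the other, for the 3 even splits of the 4 ectoderm libraries (horizontal axis). The limb split (4573 and 1517) totals 6090, and the other splits total 6267 and 6158.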

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

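The tests of depth and enrichment for hindlimb replicate 1, the comparison with other splits and the ratio within those splits at equal length were chosen after the results were seen; the ratio of the limb classes with lists of equal length was fixed before its result was seen.

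Hindlimb replicate 1 had 51510 distinct peaks, and its gap to the next ectoderm library was 0.834 of the whole range, just past Dixon's 95% critical value for 4 samples. It was 1 of 6 library measures examined, and chance gives a gap past that value in about 1 in 20 groups. Its background rate of 4.36 was the highest of the 4 ectoderm libraries, which argues against lower sequencing depth if reads were extended alike in each library. Its median summit fold over the 20977 regions called in all 4 ectoderm libraries was 4.32, below the 6.40 to 7.79 of the others, but folds belong to their own lists, so this does not decide whether reads were less enriched at open sites, which stays open. No biological explanation for a difference between replicates of 1 limb was tested.

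Forelimb-only regions were 3.01 times as many as hindlimb-only regions. With lists of equal length the ratio was 2.62, which argues against the length of the hindlimb replicate 1 list as the whole cause. In the other splits, which mix the limbs, the side without hindlimb replicate 1 had 4.84 and 5.04 times the regions of the side with it at equal length, so a difference of that library from the other ectoderm libraries apart from list length may account for the direction. The limb split totalled 6090 regions and the highest of the other splits 6267, and 3 splits are too few for a share under 0.05. A difference between the limbs stays open.

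In the 5 lists, 424 peaks lay on scaffolds outside the assembled chromosomes, a signal in entries that none of the comparisons used.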

How the results depend on the processing

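The stricter threshold for presence only was chosen after the data were seen; the other alternatives were planned. Over the alternatives, 56 of the values that answer a comparison were counted as unchanged and 35 as moved. For ectoderm shares of gene lists the numbers were 141 and 19, and for named genes 215 and 138, with 27 reversed. Counts were called unchanged up to a ratio of 1.5. Shares of small lists counted as unchanged could still differ widely, as for limb identity genes (6.06%, and 17.5% without hindlimb replicate 1). The unchanged values include some that an alternative could not alter, such as those of the replicate block. Where no reason is given, the cause was not tested. The depth of each library limits which weak peaks could be called, so a missing peak is not evidence of closed chromatin.

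At a −log10 q of 5 or more, with fewer peaks by construction, there were 2474 forelimb-only, 487 hindlimb-only, 3515 ectoderm-only and 49277 forebrain-only regions, 4.77% of forebrain-only regions lay near a gene end against 4.04% of ectoderm-only regions, the reverse of the order at the authors' threshold, 0 lists lay below the central range, and the HoxC window held 3 ectoderm-only regions. With the stricter threshold for presence only, the counts were 1531, 202, 3193 and 41686, the forebrain-only share was 3.55%, 0 lists lay below and the HoxC window held 3. With equal top lists, forebrain-only regions numbered 24074, as the longest list was shortened most, and the gene-end shares were 4.72% of ectoderm-only and 4.37% of forebrain-only regions. Within 2.5 kb of a gene end, a wider zone, they were 7.76% and 6.31%. Summit based presence gave a forebrain-only share of 3.33%, and on autosomes 0 lists lay below. Overlap of at least 50% of the shorter peak gave 51.97% and 52.7% for forelimb replicates 1 and 2, and 49.1% and 31.4% for hindlimb replicates 1 and 2. With forelimb and hindlimb libraries paired by replicate number (replicate block), the counts were 4573 and 1517, identical by construction, and deviations of libraries of the same number correlated at 0.00172. Among named genes, forelimb-only minus hindlimb-only regions were 1 for Cwc22 with the stricter threshold for presence only, and 1 for Lrp1b there and also 1 at a −log10 q of 5 or more. Ectoderm-only minus forebrain-only regions for Fry were 1 at a −log10 q of 5 or more, 6 with equal top lists and 2 with the stricter threshold for presence only.

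Leaving out each ectoderm library leaves 1 library for a limb, which raises the limb counts by construction: forelimb-only regions ranged from 5076 to 30022, hindlimb-only from 2599 to 29499 and ectoderm-only from 5615 to 10839, and the gene-end share of forebrain-only regions from 3.20% to 3.48%. Forelimb-only minus hindlimb-only regions ranged from -3 to 26 for Nrxn3, -6 to 25 for Opcml, -13 to 27 for Magi2, -12 to 28 for Ctnna3, -18 to 28 for Dlg2, -10 to 21 for Rbfox1 and -11 to 33 for Ptprd. They ranged from -27 to 14 for Tenm3, -7 to 2 for Cwc22, -8 to 5 for Fto, -8 to 2 for Lypd6b, -6 to 4 for Gm14410 and -13 to 14 for Lrp1b. The motif contrast and its alternatives were not run, as no genome sequence was used here.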

Other observations

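The ranking of genes by ectoderm share was chosen after the data were seen, and the tests on crowded loci were fixed before their results were seen. Among genes with at least 4 ectoderm-only regions, the ectoderm share was 100% at Zfp970 (9 ectoderm-only and 0 forebrain-only) and H60c (4 and 0), 87.5% at Cwc22 (14 and 2), 80% at Spin1 (4 and 1) and 75% at Sfi1 (9 and 3), against 6.83% over all genes. It was 66.7% at 1600014C10Rik (6 and 3) and 55.6% at Gm52481 (5 and 4). Amotl1, Efcab1, Eml4, Jmjd1c and Ptpn14 had 4 and 4 each. Lower in the ranking, Gja1, which encodes the gap junction protein connexin 43, had 4 and 5, Esr1, the oestrogen receptor gene, had 6 and 9, and Egfr, the epidermal growth factor receptor, had 7 and 12 (36.8%).

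At gene ends, 127 genes had a peak in all 4 ectoderm libraries and none in forebrain, 893 had one in forebrain and in no ectoderm library, and 10144 had one in all 5 libraries. Hoxb1, a gene of the early hindbrain, was in the group of 127, as was the melanocyte gene Mlana. Chromosome Y held 63, 91, 118, 72 and 17 peaks in forelimb replicates 1 and 2, hindlimb replicates 1 and 2 and forebrain.

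Ectoderm-only regions crowded at Cwc22, Zfp970, Sfi1 and Gm14410, with 35 regions in all, and 5368 ectoderm-only regions remained without these loci. The median local background at their ectoderm peaks was 3.43 times the library background rate, against 1.46 at the other ectoderm-only regions, though at Gm14410 it was 1.28. Extra copies of these loci relative to the reference would give a raised ratio. But the loci were chosen because peaks crowd there, and a local background reflects the reads around a peak. The ratio therefore cannot separate extra copies from crowding. The median rank of the peaks was at percentile 61.3. It lay below the median of all ectoderm-only regions, 76.9, and just below their lower quartile, 61.9. The rule fixed beforehand counted a median below that quartile against regulatory elements like those elsewhere, and named no interval. The bootstrap interval, 54.8 to 67.7, spans the quartile. The value thus goes against such elements but is too close to the limit to decide. Forebrain peaks had a ratio of 1.23 at Cwc22 (5 regions), 1 at Zfp970 (3 regions), 7.79 at Sfi1 (11 regions) and 2.07 at Gm14410 (1 region). The forebrain value was below that of ectoderm at Cwc22 (6.12) and Zfp970 (2.93). It was above that of ectoderm at Sfi1 (2.3) and Gm14410 (1.28). The CD1 stock is outbred, and whether embryos differed in copy number was not tested.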
